A study of Homo sapiens with 4 samples.

How the data were processed

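RNA from HuCCT1, a human cholangiocarcinoma (bile duct cancer) cell line, was profiled on 4 Affymetrix Human Gene 1.0 ST arrays, which measure whole transcripts with probes spread along the exons. The labels give 1 array each to untreated cells, cells given VPA, cells given GEM, and cells given GEM and VPA together. VPA and GEM are the labels' own abbreviations and are read here with their usual meanings for cancer cells, the histone deacetylase (HDAC) inhibitor valproic acid and the nucleoside analogue gemcitabine. Doses, exposure times, culture batches and scan dates are not given in the sources used here.

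The deposited values were log2 intensities that the authors normalized with GeneSpring GX 11.5, per the labels' series text, and with RMA, per the submitters' processing notes. RMA subtracts background, equalises the distribution of probe intensities between arrays and summarises the probes of a row, so small array-wide differences are removed before deposit and low values are compressed. The table held 28869 rows per array, with levels from about 4.38 to 14.67 and array medians of 7.87 to 7.92. Scanner files, detection calls and array quality values were not used here, and the genome build behind the rows is not given in the sources used here, so no coordinates are printed.

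Rows were named from the platform annotation. It gave 1 gene symbol to 19310 rows, several to 1752 rows and none to 7807 rows, and only rows with 1 symbol were given a gene name. Entrez IDs matched the current RefSeq gene table for 99.84% of these rows and no symbol needed updating. The 18377 genes took the mean log2 value of their rows. Of the 685 genes with more than 1 row, between 1 and 8 per comparison had rows that differed by over 1 on the log2 scale. Histone, metallothionein, actin, HLA and MAGEA genes have near-identical copies that can share probes, so their values are uncertain for the single gene. Small nucleolar and microRNA host rows are named as the annotation gives them.

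With 1 array per group there were no replicates, so single comparisons have no test, no error and no p-value. The rules for comparisons, filters, lists and named genes were fixed before the data were examined. A gene was counted as different between 2 arrays when its log2 ratio was at least 1 in size, the authors' limits of 2 and 0.5 for the ratio, and its higher value was at or above that array's median over all rows. The 5 comparisons were each drug and the combination over untreated, and the combination over each drug. The departure from additivity was the combination minus GEM minus VPA plus untreated on the log2 scale. The change with each drug was also compared between the pair of arrays without the other drug and the pair with it, since these pairs share no array. The average effect of each drug over both pairs was tested with limma (additive model with 1 residual degree of freedom per gene, moderated across genes, Benjamini-Hochberg adjustment). Its residual holds the departure from additivity as well as array noise.

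The 32 gene lists were compared with random genes. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins, and a list was said to stand apart below percentile 2.5 or above percentile 97.5. This describes these arrays and is no test, because genes are not replicates. About 8.0 of the 160 list values would stand apart if the genes of each list behaved as random draws. Genes of a list can vary together, so more could stand apart without a drug effect. Lists also share members and comparisons share arrays, so 8.0 is no benchmark for the observed count.

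Named genes were the 10 with the largest increase and the 10 with the largest decrease among genes passing the rule in each comparison (5 and 5 for the departure), up to 4 passing members of each list, and CDKN1A, DCK, CDA, RRM1, RRM2, SLC29A1, CDH1, VIM, MYC, CCND1 and BCL2L1. A further gene of this fixed set is not reported here. Any other gene named was chosen after its values were seen, and the text says so.

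The counting rule and the limma fit were checked on simulated data with noise of 0.104 (SD per array on the log2 scale), taken from the closest pair of arrays. In the simulated VPA over untreated comparison of 18377 genes, 100 of 100 genes changed by 1.5 and 100 of 100 changed by 2.0 on the log2 scale were recovered, with 0 calls among 18177 unchanged genes. In the simulated VPA average effect on 11808 genes, limma recovered 100 of 100 genes changed by 1.0, with 8 false calls. Both simulations gave all genes the same noise, and in the first the changed genes were drawn well above the level filter. They check that the steps run as written and do not give the power or error rate in the data. Alternatives covered the normalization, the level filter, the fold limit, the choice of row, the limma model and the summary of lists. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.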

Results

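Transcript levels were measured in HuCCT1 cells that were untreated, exposed to VPA, exposed to GEM, or exposed to both (GEM_VPA, the combination), with 1 array per condition. The series compares the drugs alone with the drugs together. No condition was replicated, so differences are given as sizes on the log2 scale, without error or p-value, unless limma is named. The number of arrays limits the precision of each value. All directions follow the labels as given.

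The arrays fell into 2 close pairs. The arrays labelled untreated and combination correlated at 0.996 over all 28869 rows, and those labelled VPA and GEM at 0.996 (0.9962 and 0.9955). The remaining pairs of arrays correlated between 0.984 and 0.987. The robust SD of the log2 differences over genes was 0.147 between untreated and combination and 0.158 between VPA and GEM. It was 0.264 for VPA over untreated, 0.261 for GEM over untreated, 0.253 for the combination over VPA and 0.27 for the combination over GEM.

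The first comparison set VPA alone against no drug. The array labelled VPA showed lower transcripts of DNA replication, mitosis and replication-dependent histone genes and higher transcripts of p53 target genes than the untreated array. KRTAP3-1, a hair keratin-associated protein, was 22.3-fold higher, IQGAP2, a scaffold protein, 12.7-fold higher, ANKRD1, an ankyrin repeat protein, 9.54-fold higher and FN1, fibronectin, 6.53-fold higher. IFI6, an interferon-stimulated gene, TCN1, a vitamin B12 carrier, TGM2, a transglutaminase, ACTBL2, an actin-like gene with near-identical relatives, SLC2A3, a glucose transporter, and RASGRP3, a Ras activator, were 5.12-fold to 6.39-fold higher. The largest decreases were in the histone genes H2AC14 (log2 ratio -2.60 or lower), H2AC4 (-2.43), H3C12 (-2.28), H3C1 (-2.05), H2AC13 (-1.94), H4C2 (-1.91) and H2BC14 (-1.86), in SLC7A11, the cystine transporter (-2.29), in THOC6, a subunit of the THO mRNA export complex (-1.92), and in LMNB1, lamin B1 (-1.75). ACTBL2 and RASGRP3 on the untreated array and H2AC14 on the VPA array lay below the 25th percentile of rows, where values are compressed and are not shown to be above background, so their sizes may be understated and their ranks are uncertain. In all, 464 of 11623 genes at level differed at least 2-fold, 221 higher and 243 lower. The share that was higher was 47.6%, 58.4% after quantile normalization of the columns again and 38.7% with each array centred on its median. The balance turned with the limit, with 56 higher and 15 lower at 3-fold (78.9% higher) and 771 and 1202 at 1.5-fold (39.1%).

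Of 29 measured G1/S and replication genes, 14 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.92. ORC1, of the origin recognition complex, was at -1.56, the helicase subunits MCM5 and MCM2 at -1.47 and -1.43, and POLE2, a polymerase epsilon subunit, at -1.41. Of 29 G2/M and mitosis genes, 7 were 2-fold lower and all 29 were below 0 (median -0.76), among them MAD2L1 at -1.40, CCNB1 at -1.23, KIF11 at -1.21 and BUB1B at -1.09 (-0.98 after quantile normalization of the columns again). Of 56 replication-dependent histone genes, 20 were 2-fold lower and 52 were below 0 (median -0.67). Of 24 measured DNA damage response and repair genes, 7 were 2-fold lower (median -0.62), with MSH6 at -1.27, XRCC2 at -1.23, CLSPN at -1.18 and CHEK2 at -1.11. These 4 medians lay below those of all 10000 matched random lists. Among CDK inhibitor and cell cycle brake genes, whose median of -0.03 did not stand apart, CDKN1A and BTG1 (1.12) were higher and RBL1 (-1.10) was lower.

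Of 23 p53 target genes, 4 were at least 2-fold higher and 22 were above 0, with a median log2 ratio of 0.54, above all 10000 matched random lists. TP53INP1 was at 2.20, CDKN1A, the CDK inhibitor p21, at 1.46, PLK3 at 1.29 and GDF15 at 1.29. The HDAC inhibitor response list had a median of 0.39 over 18 genes, also above all matched lists, with CDKN1A, CCN2 (1.15), GSN, which encodes gelsolin (1.13), and CRIP2 (1.01, and 0.96 with each array centred on its median) at least 2-fold higher. CDKN1A and CCN2 belong to other lists as well. Interferon-stimulated genes had a median of 0.24 over 29 genes, 4 of them 2-fold higher, with IFI6 at 2.67 and SAMD9 at 1.89. Epithelial genes had a median of 0.31 over 22 genes, of which only KRT7, keratin 7, passed the 2-fold rule (1.97). CDH1, E-cadherin, was at 0.86. Smaller list medians above the upper percentile limit were 0.22 for fatty acid oxidation and PPAR genes, 0.13 for immediate-early and ERK feedback genes (CCN1 1.87, JUN 1.44), 0.18 for drug efflux transporters, 0.14 for Wnt and TGF-beta response genes and 0.13 for NF-kB and cytokine genes. In the last list NFKB1 (-1.31) and NFKBIA (-1.08), its only members past the rule, were lower, and its median was -0.003 over members at level alone. NFKBIA fell just short of the rule after quantile normalization of the columns again. By its mean of 0.08 the NF-kB list was at percentile 88.7. The Wnt and TGF-beta list by its mean (0.14, percentile 97.2) and the drug efflux list with 1 row per gene (0.18, percentile 97.46) kept their size and lay just under the limit. Leukocyte marker genes, a check for other cells, were also above the upper limit (median 0.19, percentile 99.64). Of these 13 genes, 11 were above 0 and 0 passed the 2-fold rule. Over the members at level alone their median was larger, 0.45, at percentile 96.4. Unfolded protein and ATF4 response genes had a median of -0.31 (percentile 0.23), with SLC7A11, ASNS (-1.26) and PSAT1 lower. Ribosomal proteins, the control list, had a median of -0.25 (percentile 0.06) with 0 of 58 genes past the rule. The control list thus moved further than the interferon-stimulated, fatty acid oxidation, leukocyte and drug efflux lists, in the other direction. It also moved further than the Wnt and TGF-beta, immediate-early and NF-kB lists. Shifts of that size are thus not specific to those lists here.

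**Figure D1:**
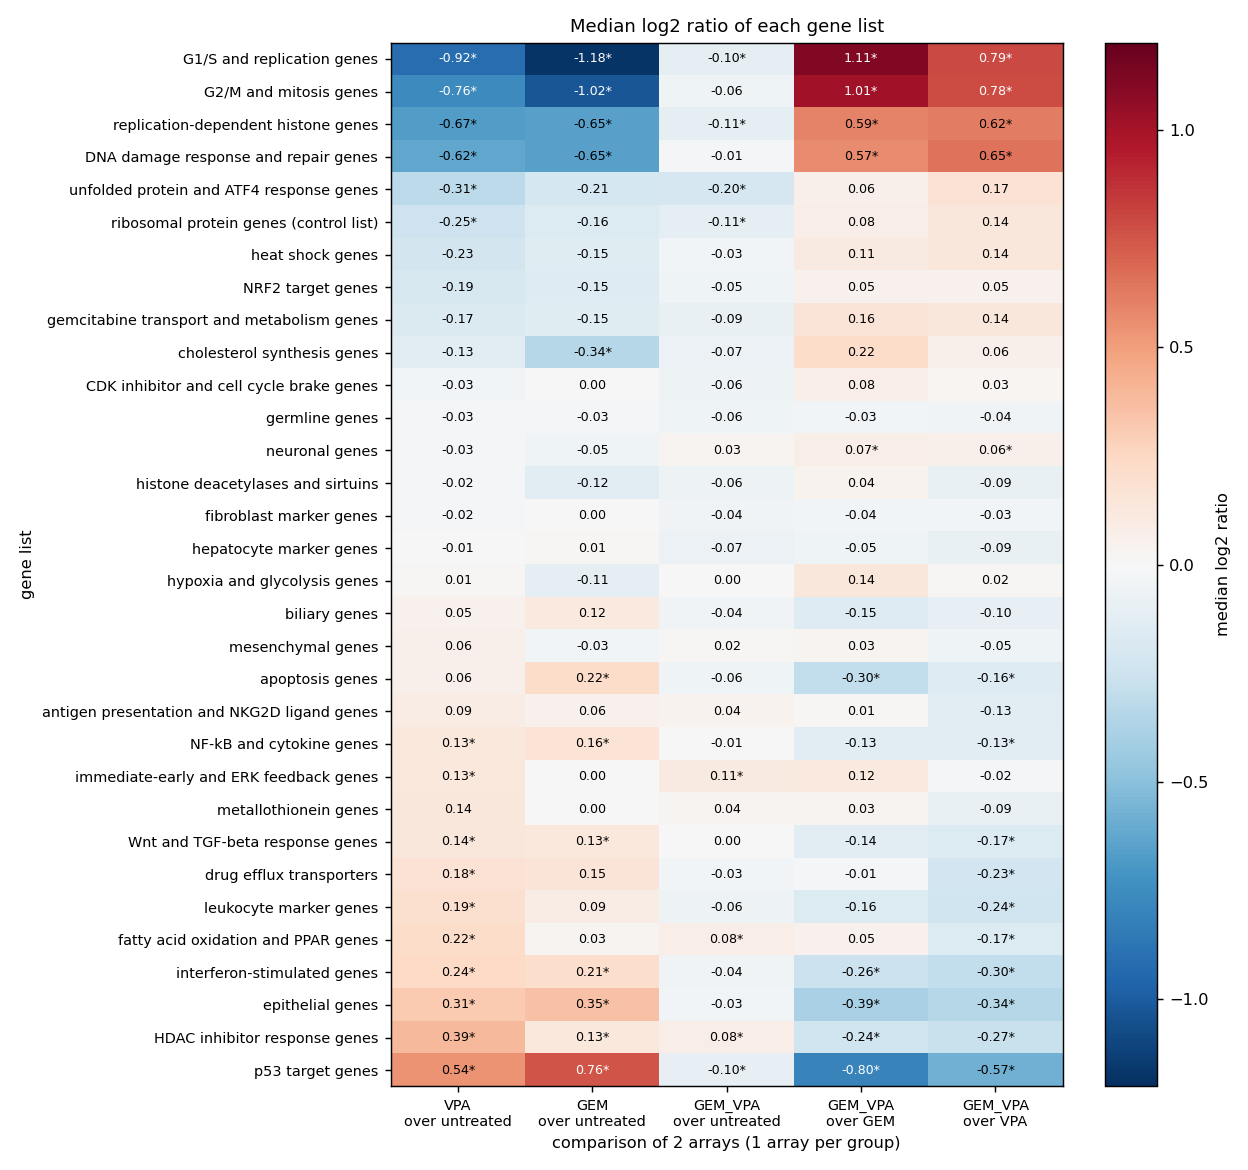
Median log2 ratio of each of the 32 gene lists (rows) in the 5 comparisons of 2 arrays (columns), with 1 array per group. Colour and number give the median, and an asterisk marks a list outside the percentile limits among 10000 matched random lists; the G1/S list runs from -1.18 for GEM over untreated to 1.11 for the combination over GEM.

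The next comparison set GEM alone against no drug. The array labelled GEM showed lower replication, mitosis, histone and repair transcripts and higher p53 target transcripts than the untreated array. KRTAP3-1 was 22.1-fold higher. ARRDC4, an arrestin-domain protein, was 6.87-fold higher, the adhesion protein CEACAM1 5.99-fold, the iron-siderophore binder LCN2 5.30-fold, CLTRN, collectrin, at least 5.23-fold and TP53INP1 5.19-fold. RASGRP3, ABCA12, a lipid transporter, FXYD3, a regulator of the sodium pump, and IQGAP2 were at least 4.61-fold higher. CLTRN and RASGRP3 on the untreated array and H2BC13 on the GEM array lay below the 25th percentile of rows, so their sizes may likewise be understated. The histone genes H3C12 (log2 ratio -2.61), H2BC14 (-2.59), H2AC4 (-2.50), H4C2 (-2.25), H2BC13 (-2.01 or lower) and H2AC15 (-1.99) were lower, as were the non-coding RNA DLEU2 (-2.31), SLC7A11 (-2.27), LMNB1 (-1.97) and INSIG1, a regulator of sterol synthesis (-1.95). In all, 521 of 11599 genes at level differed at least 2-fold, 172 higher and 349 lower.

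Of the 29 G1/S and replication genes, 17 were 2-fold lower (median -1.18), with POLE2 and MCM6 at -1.85, ORC1 at -1.73 and POLA1, the catalytic subunit of polymerase alpha, at -1.72. Of the 29 G2/M genes, 17 were 2-fold lower (median -1.02), among them KIF11 at -1.55, MAD2L1 at -1.51, CCNB2 at -1.47 and BUB1B at -1.42. Histone genes had a median of -0.65, with 21 of 56 lower and 2 higher. The repair list also had a median of -0.65, with 9 of 24 lower, including FANCI at -1.55 and MSH6 at -1.49. Of the 23 p53 targets, 7 were 2-fold higher and all 23 were above 0 (median 0.76), with TP53INP1 at 2.38, CDKN1A at 1.87, TP53I3 at 1.82 and GDF15 at 1.51. These 5 medians lay outside all 10000 matched random lists. Apoptosis genes had a median of 0.22 (percentile 99.98), with FAS, the death receptor and a p53 target, the only member past the rule (1.23). Epithelial genes (median 0.35; KRT7 1.60), interferon-stimulated genes (median 0.21; IFI6 2.01), NF-kB and cytokine genes (median 0.16), HDAC inhibitor response genes (median 0.13; CDKN1A, H2BC12 1.55, H2BC21 1.19) and Wnt and TGF-beta response genes (median 0.13) were also above the upper percentile limit. The mean of the Wnt and TGF-beta list was about 0 and did not stand apart, and its members past the rule, ID1 (-1.07, and -0.98 after quantile normalization of the columns again) and TGFB2 (-1.02), were lower. Over members at level alone the NF-kB list was at 0.13 (percentile 94.3) and the Wnt and TGF-beta list at 0.13 (percentile 95.7). Cholesterol synthesis genes were below percentile 2.5 (median -0.34, all 18 below 0). Ribosomal proteins, the control list, had a median of -0.16 (percentile 2.54), with 49 of 58 genes below 0. The control list moved about as far as the NF-kB list, in the other direction. It moved further than the HDAC inhibitor response and Wnt and TGF-beta lists. Shifts of that size are thus not specific to those lists here.

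Genes that take up, activate or inactivate gemcitabine did not stand apart as a list in any of the 5 comparisons, with medians of -0.17 for VPA and -0.15 for GEM over untreated. CDA, the deaminase that inactivates gemcitabine, was at 1.36 with VPA and 1.27 with GEM. DCK, the kinase that activates it, was at -0.66 with VPA and -1.06 with GEM, and the latter was -0.97 after quantile normalization of the columns again. RRM1 and RRM2, the ribonucleotide reductase subunits, were at -0.42 and -0.40 with VPA and at -0.77 and -0.67 with GEM. The nucleoside transporter SLC29A1 was at -0.42 and -0.36. DUT, which hydrolyses dUTP, was at -1.33 with VPA and at least 2-fold lower with GEM, and TYMS, thymidylate synthase, at -1.12 and -1.18. VIM, MYC, CCND1 and BCL2L1 lay between -0.23 and 0.29 in both comparisons.

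The arrays labelled VPA and GEM shared 285 of their 2-fold differences from untreated. Of these genes, 118 were higher on both and 167 lower on both, while 0 genes past the rule on both went opposite ways. Independent lists of these sizes would share 3.24 and 7.23. Both comparisons use the same untreated array, which by itself gives a correlation of 0.5 across genes in simulations without effects (0 shared 2-fold genes on average), against 0.861 observed. The covariance was 0.130 against 0.0108 simulated. The simulated values include the shared array at a noise SD of 0.104, so part of the excess may come from that array if it departed further.

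The combination was also set against no drug. On the array labelled combination, 17 of 11489 genes at level differed at least 2-fold from untreated, 14 higher and 3 lower. CNTN1, a neuronal adhesion protein, was 3.00-fold higher, SPP1, osteopontin, 2.79-fold, IQGAP2 2.67-fold and SNAI2, the transcription factor Slug, 2.46-fold. ZCCHC12, SSBP2, TGM2, SH3BGRL2, SGPP2 and TMOD2 were 2.21-fold to 2.45-fold higher. FN1 was at 1.13. TNFSF18, the GITR ligand, was 3.20-fold lower, the small nucleolar RNA SNORD41 2.19-fold lower and the adhesion receptor ADGRF1 2.13-fold lower. CDKN1A was at -0.12, CDA at -0.03, DCK at -0.16, RRM1 at 0.01, RRM2 at -0.04 and CDH1 at 0.21. No replication, mitosis, histone, repair or p53 gene of the fixed lists passed the 2-fold rule. Their medians were -0.10 (G1/S, percentile 0.88), -0.06 (G2/M, percentile 11.8), -0.11 (histones, percentile 0.0, 36 of 56 genes below 0), -0.01 (repair, percentile 58.5) and -0.10 (p53 targets, percentile 1.68). The histone, G1/S and p53 target lists were thus below percentile 2.5, and the G1/S list had a mean of -0.07 at percentile 4.56. Lists above the upper percentile limit were HDAC inhibitor response genes (median 0.08), immediate-early and ERK feedback genes (0.11) and fatty acid oxidation and PPAR genes (0.08). Unfolded protein and ATF4 response genes (-0.20) and ribosomal proteins (-0.11, percentile 0.0, 50 of 58 genes below 0) were also below percentile 2.5. Ribosomal proteins are the control list and moved at least as far as the histone, G1/S and p53 target lists. Shifts of this size are thus not specific to those lists here. The lists above the upper limit shifted by no more than the control list did, in the other direction.

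The combination was then set against each drug alone. Over GEM, 626 of 11645 genes differed at least 2-fold on the combination array, 419 higher and 207 lower. DLEU2, PRKAR2B, a regulatory subunit of protein kinase A, H3C12, ENPP1, an ectonucleotide pyrophosphatase, H2BC14, SLC7A11, LRRCC1, H2AC4, H4C2 and CHN1 were 4.17-fold to 5.99-fold higher. KRTAP3-1 was 19.4-fold lower and LCN2 8.06-fold lower, and ARRDC4, CEACAM1, TP53INP1, PTAFR, FXYD3, KLK5, ABCA12 and TP53I3 were 4.96-fold to 6.72-fold lower. G1/S genes had a median of 1.11 with 16 of 29 genes higher, led by POLA1 at 2.02 and POLE2 at 1.80. G2/M genes had a median of 1.01 with 16 of 29 higher, led by TTK at 1.53. Histone genes had a median of 0.60 with 16 higher and 2 lower, and repair genes 0.57 with 10 higher. The p53 targets had a median of -0.80 with 7 of 23 lower, including CDKN1A at -1.99 and GDF15 at -1.88. Apoptosis (-0.30), epithelial (-0.39), interferon-stimulated (-0.26) and HDAC inhibitor response genes (-0.24) were below percentile 2.5. All 13 leukocyte markers were also below 0 (median -0.16, percentile 2.52), with LYZ at -1.72 and CD68 at -1.28 past the rule. Neuronal genes had a median of 0.07 (percentile 99.5), with L1CAM, their only member past the rule, lower (-1.28), and their mean of 0.09 was at percentile 93.8. Over members at level alone their median was 0.22 (percentile 92.8). The control list had a median of 0.08 (percentile 69.7), so the neuronal median over all members was no larger than its own.

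Over VPA, 367 of 11612 genes differed at least 2-fold on the combination array, 172 higher and 195 lower. The share that was higher was 46.9%, 58.0% with each array centred on its median and 41.4% after quantile normalization of the columns again. It was 23.5% at 3-fold and 60.8% at 1.5-fold. SLC7A11, H3C12, H2AC4, H3C1, DLEU2, H4C2, SLC7A2, H2BC14, H4C4 and POLA1 were 3.08-fold to 5.17-fold higher. KRTAP3-1 was 19.5-fold and ANKRD1 10.7-fold lower, and SLC2A3, KRT7, TCN1, IFI6, TP53INP1, ACTBL2, ARRDC4 and IQGAP2 were 4.77-fold to 5.94-fold lower. G1/S genes had a median of 0.79 (11 of 29 higher), G2/M genes 0.78 (5 higher), histone genes 0.62 (16 of 56 higher, 1 lower) and repair genes 0.65 (7 of 24 higher). The p53 targets had a median of -0.57 with 5 lower. Epithelial (-0.34), interferon-stimulated (-0.30) and HDAC inhibitor response genes (-0.27) were at percentile 0.02 or below. DHRS2, a dehydrogenase of the HDAC inhibitor list, was higher (1.02). Leukocyte markers (-0.24; CD68 -1.28), drug efflux transporters (-0.23; ABCC3 -1.32), fatty acid oxidation and PPAR genes (-0.17; HADH, their only member past the rule, 1.14), Wnt and TGF-beta response genes (-0.17), apoptosis genes (-0.16) and NF-kB genes (-0.13) were below percentile 2.5. Neuronal genes were above the upper percentile limit (0.06), with L1CAM lower. The control list had a median of 0.14 (percentile 93.6), so the NF-kB and neuronal shifts were no larger than its own. After quantile normalization of the columns again, the fatty acid oxidation (-0.14, percentile 2.68), NF-kB (-0.10, percentile 2.87) and neuronal lists (0.08, percentile 97.2) lay just inside the limits. By their means, the NF-kB list was at -0.11 (percentile 7.08), the neuronal list at 0.03 (percentile 83.6), the fatty acid oxidation list at -0.05 (percentile 11.6) and the Wnt and TGF-beta list at -0.12 (percentile 4.59). Over members at level alone, the drug efflux list was at -0.16 (percentile 7.94), the NF-kB list at -0.07 (percentile 21.6), the fatty acid oxidation list at -0.08 (percentile 7.51) and the neuronal list at 0.19 (percentile 93.4).

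**Figure D2:**
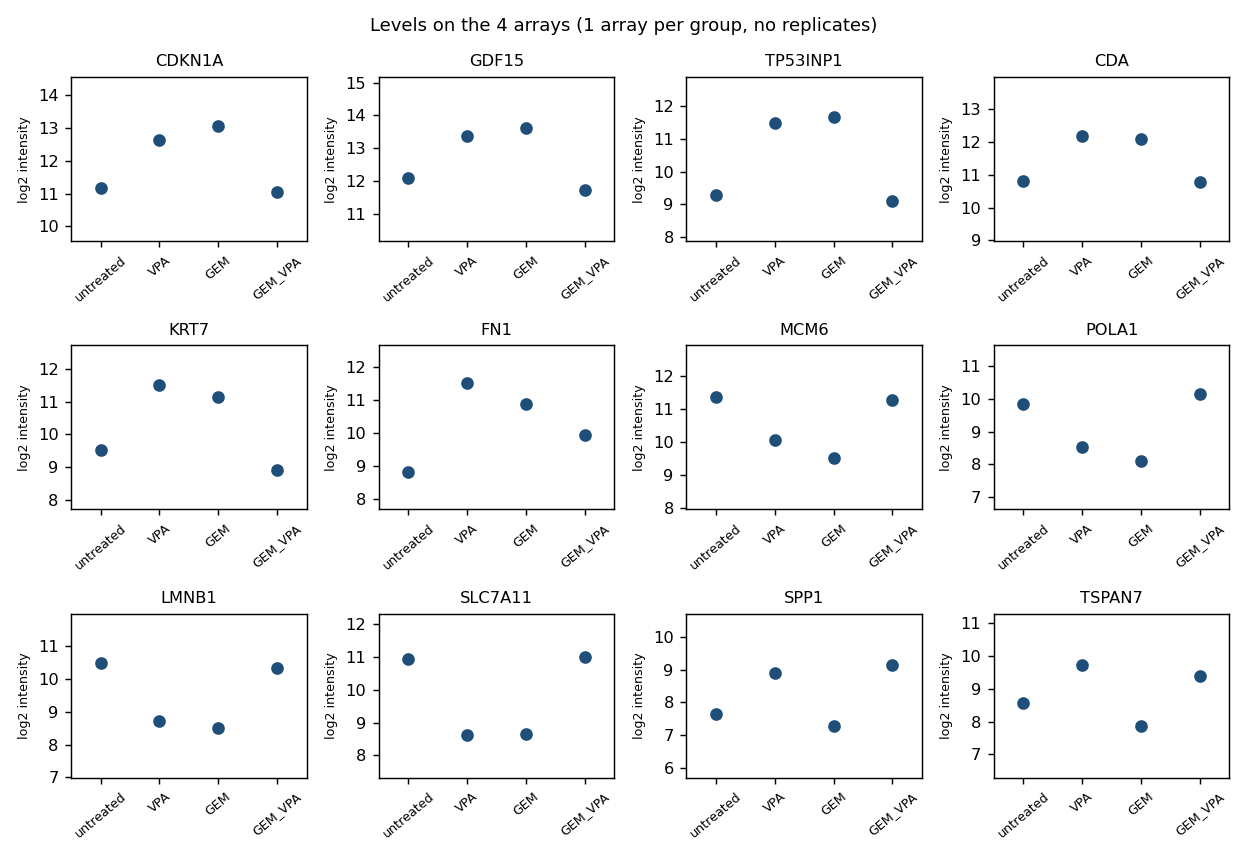
Log2 intensity of 12 genes (TSPAN7 chosen after its values were seen) on the 4 arrays, 1 point per array, with no replicates and the same 5-unit span on each vertical axis. CDKN1A is at 11.2 on the untreated array, 12.6 with VPA, 13.0 with GEM and 11.1 with both, while SPP1 and TSPAN7 are higher on both arrays that hold VPA.

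The change with each drug was compared without and with the other drug. As labelled, the change with VPA was opposite in the pair of arrays without GEM and the pair with it. Exchanged labels or a batch of arrays could give the same pattern, for both drugs and for the departures from additivity. These explanations are weighed among the results flagged for a closer look. Across 11808 genes at level, the log2 ratios of VPA over untreated and of the combination over GEM had a Spearman correlation of -0.67, and these pairs share no array. Of genes past the rule in both pairs, 206 went opposite ways and 2 went the same way, SPP1 and TSPAN7, a tetraspanin, both higher. TSPAN7 was chosen after its values were seen. SPP1 was at 1.26 and 1.85 and TSPAN7 at 1.16 and 1.54. Independent lists would share 7.84 higher and 4.26 lower genes. For GEM the Spearman correlation was -0.88, with 249 genes opposite and 0 the same way, where independent lists would share 2.51 higher and 5.76 lower genes. Genes are not independent replicates, so these values carry no p. The departure from additivity was at least 2-fold in 2402 of 11808 genes, 1531 higher and 871 lower on the combination array than the sum of both drugs predicts. It was largest for H3C12 (4.82), SLC7A11 (4.64), H2AC4 (4.62), H2BC14 (4.26) and DLEU2 (4.06) among higher genes and for KRTAP3-1 (-8.76), ARRDC4 (-5.06), ANKRD1 (-4.92), TP53INP1 (-4.75) and CEACAM1 (-4.74) among lower genes. CDKN1A departed by -3.45, CDA by -2.66 and CDH1 by -1.64. The level predicted for KRTAP3-1 (9.12 on the untreated array plus 4.48 and 4.47) lies above 14.67, the highest value on any array. Some of its departure was thus forced by the top of the scale. The levels predicted for H2AC4 and SLC7A11 lie below the 25th percentile of rows, where values are compressed. Part of their departures may therefore come from the scale. Without replicates the departure of a single gene has no test.

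**Figure D3:**
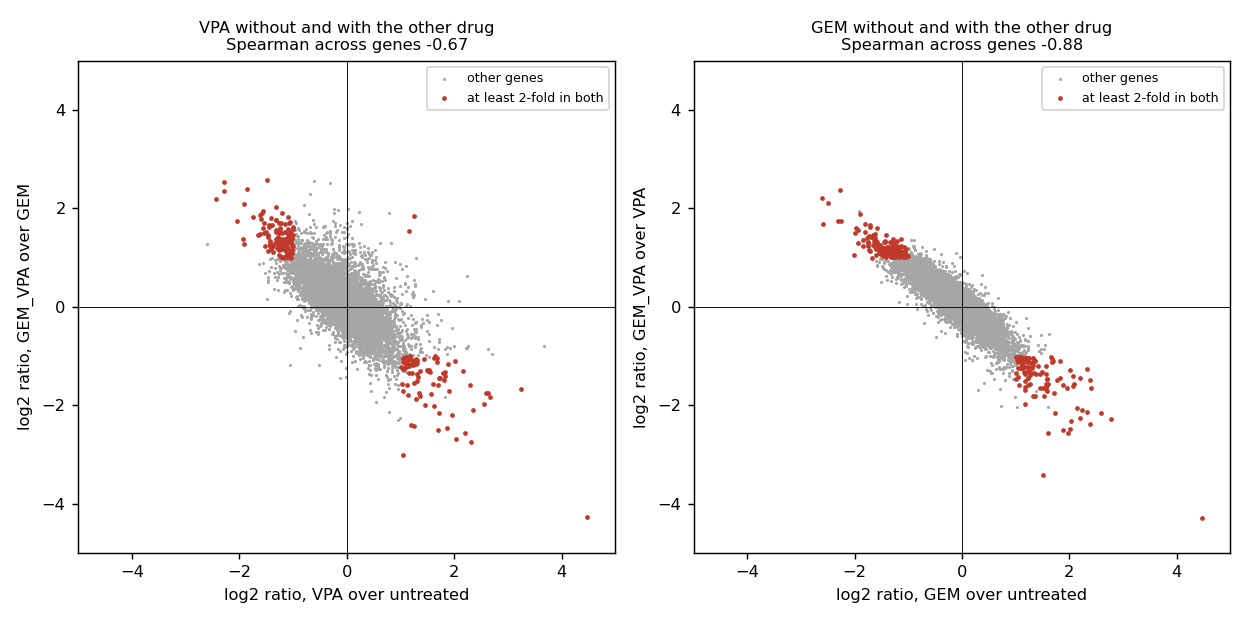
Log2 ratio of each gene at level without the other drug (horizontal) and with it (vertical), for VPA on the left and GEM on the right; red points are at least 2-fold in both pairs of arrays. The points run from upper left to lower right, with 206 opposite and 2 same-way genes for VPA and 249 and 0 for GEM.

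Averaged over both pairs, 0 genes passed an adjusted p of 0.05 in limma for VPA or for GEM (smallest adjusted p = 1 for each). At an unadjusted p under 0.05 there were 22 genes for VPA and 0 for GEM. Both lie far below a share of 0.05 of the 11808 genes, which well-calibrated p-values would give without any effect. The residual holds the departures and enlarges the error, so the test had little room to call a gene. The 0 calls are thus no evidence against an average effect, and the 22 genes are not hits. The prior SD of 0.301 came from residuals that hold the departures from additivity. For VPA the same fit recovered all simulated changes of 1.0, but with no departure present and the same noise for all genes. The average change with VPA was 1.55 ± 0.30 (limma's moderated SE, 2 arrays with and 2 without) for SPP1 and 1.35 ± 0.28 for TSPAN7. The variance behind this SE weights the value pooled across genes by 3.17 degrees of freedom and the gene's own by 1. It is thus mostly not the spread of the single gene.

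The remaining lists stood apart in none of the 5 comparisons. Their medians for VPA and GEM over untreated were -0.02 and -0.12 for histone deacetylases and sirtuins, -0.19 and -0.15 for NRF2 targets, -0.23 and -0.15 for heat shock genes, 0.01 and -0.11 for hypoxia and glycolysis genes, 0.06 and -0.03 for mesenchymal genes and 0.05 and 0.12 for biliary genes. They were 0.09 and 0.06 for antigen presentation and NKG2D ligand genes, 0.14 and 0.00 for metallothioneins and -0.03 and -0.03 for germline genes. Markers of other cell types had medians of -0.01 and 0.01 (hepatocyte) and -0.02 and 0.00 (fibroblast). Members past the rule went both ways. With VPA, FN1, ACTA2 (1.60), SNAI2 (1.12), KRT7, SPP1, HLA-DPA1 (2.00), HLA-DMA (1.52), CD274 (1.22) and the small heat shock protein HSPB8 (1.40) were higher, while SLC7A11 and the chaperones HSPE1 (-1.36) and HSPH1 (-1.05, and -0.94 after quantile normalization of the columns again) were lower. With GEM, FN1 (2.08), ACTA2 (1.56), KRT7, the reductase AKR1B10 (1.43), HLA-DPA1 (1.17, and 0.97 with 1 row per gene) and the glucose transporter SLC2A1 (1.04, and just short of the rule with each array centred on its median) were higher, while SLC7A11, HSPE1 (-1.22) and the NKG2D ligand ULBP1 (-1.32) were lower. Over all lists and comparisons, 61 of 160 values stood apart.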

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

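The tests of exchanged labels, of culture batches and of opposed drug effects were chosen after the array correlations had been seen, and the tests on neuronal genes and on rows of low level were set before their results were seen.

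Genes moved in opposite directions with the same drug depending on the other drug: 206 genes for VPA and 249 genes for GEM were at least 2-fold up in one pair of arrays and 2-fold down in the other. With 1 array per group the difference was not tested. Lists stood apart in opposite directions in the same way. With VPA added to GEM, the medians were 1.11 for G1/S and replication genes, 1.01 for G2/M genes, 0.60 for histone genes, 0.57 for repair genes, -0.80 for p53 targets, -0.39 for epithelial genes, -0.26 for interferon-stimulated genes and -0.24 for HDAC inhibitor response genes, each against the sign seen with VPA alone. With GEM added to VPA, they were 0.79, 0.78, 0.62, 0.65, -0.57, -0.34, -0.30 and -0.27 for the same lists, and also -0.16 for apoptosis, -0.13 for NF-kB and -0.17 for Wnt and TGF-beta genes.

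The pattern behind these values is that the arrays labelled untreated and combination are alike and those labelled VPA and GEM are alike. A candidate explanation is that the labels of the VPA and combination arrays were exchanged: the combination minus untreated and VPA minus GEM, which share no array, agreed across genes (Spearman 0.452, 0.436 to 0.467 over resampled genes), as they also would with correct labels, a batch of these sets of arrays and a steady VPA effect larger than that of GEM, so this does not single out an exchange, while neuronal genes as a sign of the drug separating the close arrays were between the limits set beforehand, at percentile 93.3 and 94.8. The robust SD of the departure from additivity over 11808 genes at level was 0.694 as labelled (2402 genes departing 2-fold), 0.176 with untreated set opposite the array labelled VPA (13 genes) and 0.282 with untreated set opposite the array labelled GEM (274 genes), but any arrangement other than the labelled one shrinks the departure once the arrays pair in this way, the arithmetic is the same if the untreated and GEM labels were exchanged instead, and nothing in the tables checks a label directly. An array batch that shifts every row was left open. In the 7217 rows of lowest level the spread between the sets of arrays was 1.24 times that within them. Resampling rows gave 1.19 to 1.29, which likewise holds no variation between arrays or cultures. The value of 1.24 lay between the limits of 1.2 and 1.5 set beforehand, while the spread was 3.42 times in the 7218 rows of highest level. A culture or harvest batch is also open, with 0 batch or date labels given. The biological explanation, drugs that oppose each other in the combination, cannot be told apart from these with 1 array per group: the 285 genes changed the same way by each drug alone kept a median of 10.2% of that change (quartiles -0.7% and 21.4%), but they were picked for showing the pattern.

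Rows without a gene name held differences as well: 50 such rows at level were at least 2-fold different in VPA over untreated, 57 in GEM over untreated and 3 in the combination over untreated.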

How the results depend on the processing

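All alternatives reported in this part were planned, except that the counts of opposite changes were added after seeing the data. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers. No named gene past its limit reversed. Of list values under an alternative, 723 kept their side of the percentile limits, 45 newly stood apart and 20 no longer did. In 2 the direction turned and the list no longer stood apart, to -0.003 for NF-kB genes in VPA over untreated with members at level alone and to -0.0004 for Wnt and TGF-beta genes in GEM over untreated with means; the cause was not tested. Some medians near 0 that did not stand apart also changed sign. Lists that lost their call in more than 1 setting were the NF-kB, neuronal, fatty acid oxidation, Wnt and TGF-beta, and drug efflux lists; restricting to genes at level left some lists with too few members, which gave no value. Of named genes, 989 values kept their side of the 2-fold limit, 18 fell under it and 1 passed it. Limma called 0 genes for either drug in every alternative tried, with 4 to 178 genes for VPA and 0 to 4 for GEM at an unadjusted p under 0.05, and list values standing apart ranged from 61 to 75. Both kinds of renormalization, the 25th percentile filter, no filter and the choice of row moved no total of 2-fold genes in the 5 comparisons, the departure or the opposite changes by over 1.5 times. At an unadjusted p under 0.05, limma had 72 genes for VPA and 4 for GEM with no filter. It had 53 and 1 with the 25th percentile filter, against 22 and 0. All these unadjusted counts lie below a share of 0.05 of the genes fitted, so they are not hits. Counting every row of the table without a filter gave 38 differences for the combination over untreated. With the level filter at the 75th percentile, fewer genes were tested, and 5 had an average VPA change of at least 2-fold. The counts were then 9 for the combination over untreated, 408 for the combination over GEM and 0 for same-way VPA changes. With a limit of 1.5-fold they were 1973 (VPA over untreated), 1974 (GEM over untreated), 184 (combination over untreated), 2148 (combination over GEM), 1750 (combination over VPA), 4842 (departure), 26 (same-way VPA), and 1047 and 1286 (opposite for VPA and GEM). With a limit of 3-fold they were, in the same order, 71, 82, 1, 105, 51, 885, 0, and 27 and 32. Both shifts follow from the limit itself, and the same-way count for GEM stayed at 0. The average change was at least 2-fold in 13 genes for VPA and 0 for GEM, and leaving out any array leaves a single pair, with 466 to 630 genes for VPA and 371 to 527 for GEM and no test. Depth cannot be judged without scanner signal over background, and rows near the bottom of the scale are compressed.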

Other observations

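The genes in this part were chosen after their values were seen. Averaged over both pairs, 13 genes differed at least 2-fold between arrays with and without VPA, none past limma's adjusted p. Those higher with VPA were SPP1 (1.55), IQGAP2 (1.44), CNTN1 (1.43), TSPAN7 (1.35), SSBP2 (1.35), ZCCHC12 (1.14), ENPP1, CPM and SH3BGRL2 (1.11, 1.08 and 1.06), the serine protease TMPRSS11E (1.10), the calcium-binding protein CALB2 (1.00) and the class II antigen gene HLA-DPB1 (1.00), and TNFSF18 was lower (-1.12). TMPRSS11E on the untreated array lay below the 25th percentile of rows, where values are compressed, so its size may be understated. The direction was the same in both labelled pairs for SPP1, CNTN1, TSPAN7, SSBP2, ZCCHC12, TMPRSS11E, CPM, SH3BGRL2, CALB2, HLA-DPB1 and TNFSF18, and opposite for IQGAP2 and ENPP1. For some the change lay almost wholly in 1 pair. Without and with GEM, CALB2 was at 0.02 and 1.99, TMPRSS11E at 2.10 and 0.11, HLA-DPB1 at 1.88 and 0.12 and CPM at 0.23 and 1.92. The smaller value of each lay below the robust SD of its comparison (0.264 and 0.27). The other same-direction genes changed by more than that in both pairs. Since the arrays labelled VPA and combination enter this average alike, it does not depend on which of them is which.

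Set directly against each other, the arrays labelled VPA and GEM differed at least 2-fold in 35 genes, 31 higher with VPA and 4 lower. Of these, 33 had the same sign in the combination over untreated, and 16 of the 17 genes past the rule there had the same sign in VPA over GEM. Past the rule in both were 4 genes, all higher (SPP1, IQGAP2, CNTN1 and SSBP2), where independent lists would share 0.037.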
